A study of Mus musculus with 6 samples.

How the data were processed

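Each of the 6 libraries has unique molecular identifier (UMI) counts per gene and cell barcode from droplet sequencing of CD11b bead-sorted cells. The authors made these counts with Cell Ranger 7.2.0 on the mm10 build, per the labels and the file headers, and deposited them as whole numbers without normalization, already limited to barcodes taken as cells. The annotation release and the handling of intron reads are not given in the sources used here. The sorted cells came from collagenase digests of the ipsilateral hemisphere, per the labels' protocols, and were put through 10x Genomics single-cell 3' chemistry.

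The 6 libraries held 7500 and 6828 barcodes (Sham), 8209 and 10186 (vehicle) and 10000 and 9020 (4-OI). Their UMI totals were 27413705 and 25575337, 36313234 and 35141470, and 37024724 and 36553526. Cells with at least 300 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored against simulated cell pairs, and 3643 barcodes, a share of 0.8% per 1000 barcodes of a library, were removed. Counts per cell were scaled and logged, and 2000 variable genes gave 30 principal components, a graph of 20 neighbours and 26 Leiden clusters at resolution 1 (numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2). Clusters took a class name from marker lists when at least 3 markers reached 50 CPM (counts scaled to the library total) and the score was at least 0.1 and 1.5 times that of the next class. This named 25 clusters in 11 classes, and cluster 24 stayed unnamed. The names describe marker expression, so cells are called microglia-like and so on. They were rebuilt here and can differ from the study's own annotation. Microglia-like clusters held among their top markers Slc2a5 and Upk1b (cluster 0), P2ry12, Tmem119 and Gpr34 (1), Olfml3 (2), Ccl12 (4), Lpl and Mmp12 (7), the heat shock gene Hspa1a (14) and the interferon response gene Ifit2 (15), and cluster 5 held shallow cells. Neutrophil-like clusters held Stfa2l1 (3), Cxcl2 (6), Il1r2 (8), Ltf and Ngp (10) and Fcnb and Camp (21), and monocyte/macrophage-like clusters Arg1 and Fn1 (9) and Ace and Treml4 (20).

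Counts were summed per library over the cells of a class, since cells of a library are not replicates. The 3 classes with at least 30 cells in every library among the myeloid cells were tested: microglia-like, monocyte/macrophage-like and neutrophil-like. Their summed UMIs per library ran from 16098616 to 21443970, from 473507 to 3244389 and from 932329 to 10749468. Monocyte/macrophage-like cells numbered only 104 and 86 in the Sham libraries. Tests were edgeR 4.0.16 quasi-likelihood F tests (R 4.3.3, limma 3.58.1) with filterByExpr, TMM scaling and 1 term per group over all 6 libraries, which leaves 3 residual degrees of freedom. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in the class. The contrasts were vehicle against Sham (injury) and 4-OI against vehicle. Class shares were tested with edgeR on cell counts per library, with kept cells as library size. An exact permutation test of 2 against 2 libraries cannot give a p under 0.333, so none was used. Where a library is left out, the lone library of its group is assumed to vary like the other groups.

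Gene lists, 27 in all, were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, over members that were tested (at least 5), and adjusted over lists and classes of a contrast. They cover NRF2 targets, ATF4 stress, interferon response, NF-kB and cytokines, inflammasome, glycolysis and hypoxia, oxidative phosphorylation, homeostatic and disease-associated microglia, alternative activation, antigen presentation, phagocyte oxidase, lysosome, cholesterol synthesis, cholesterol efflux, cell cycle, immediate early genes, neutrophil granules, neutrophil activation, mitochondrially encoded genes and markers of 7 other cell types. Neuron, oligodendrocyte and endothelial markers had under 5 tested members in every class and were not tested, and astrocyte and erythroid markers reached 5 only in microglia-like cells. A list "placed" lower or higher is one that camera called, whatever its single genes did.

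The text names, per contrast and class, the 4 largest rises and falls among genes that passed, whose groups did not overlap and whose mean reached 20 CPM in the higher group. Unnamed transcripts, mitochondrial genes and genes under 10% of their CPM in another tested class were set aside. This 10% is a preset limit for free RNA and not a measured rate. Genes under it are called within reach of free RNA. Acod1, Hmox1, Nqo1, Gclm, Il1b and Tnf are given always, and each list gives its largest members. These rules, the lists, the tests and most alternatives were set before the data were examined. Folds against a group at 0 counts use a floor of 3 counts over the group. Where a library left out leaves Sham with few counts of a gene, its fitted change depends on the prior count of edgeR.

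On simulated counts with the depth and spread of each class, 2-fold changes were found in 82.1% and 80.6% of genes in microglia-like cells (injury, then 4-OI), 28.8% and 63.1% in monocyte/macrophage-like and 22.2% and 36.4% in neutrophil-like cells. Wrong calls made up 11.1% and 4.85%, 5% and 9.42%, and 1.64% and 7.32% of the calls. The biological coefficient of variation was 6.28%, 10.2% and 16.4%.

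Alternatives were RLE size factors, DESeq2 1.42.0, other count filters, only 2 groups, the replicate block, a fold threshold of 1.2, looser (200 genes, 20%) and stricter (500 genes, 5%) cell filters, no doublet removal, resolution 0.5, thinning to equal median depth, removal of genes within reach of free RNA, and each library left out. Added after seeing the data were fits without the microglia cluster of lowest marker score (cluster 7), without the neutrophil clusters marked by granule genes (10 and 21), with equal cell numbers, with crossed pairing of libraries, and with 1 vehicle library for each contrast in the correlation.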

Results

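RNA was counted in single cells that carried CD11b, an integrin subunit of microglia, monocytes, macrophages, neutrophils and natural killer cells, and that had been taken with magnetic beads from the ipsilateral hemisphere of male C57BL/6 mice. The Sham group came from 8 mice. The vehicle group came from 10 mice with controlled cortical impact, a model of traumatic brain injury, that received 40% cyclodextrin. The 4-OI group came from 10 mice with the same impact that received 4-octyl itaconate, a cell-permeable derivative of the macrophage metabolite itaconate, at 10 mg/kg by intraperitoneal injection. Dosing was 1 hour and tissue collection 12 hours after the impact. Each group gave 2 libraries, which the series text describes as a random division of the group's cells. By that text every p-value here measures only the spread between samples of a pool and not between mice. The libraries of a group differ by more than such a division gives, so what that spread covers is not settled. The Sham labels also list 40% cyclodextrin, while the series text describes dosing of injured mice only. The libraries held 6828 to 10186 barcodes and 25575337 to 37024724 unique molecular identifiers (UMIs). After filtering, 47438 of 51743 barcodes were kept. Median UMIs per barcode, before filtering, ran from 2931.5 in vehicle library 2 to 3875 in vehicle library 1.

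The first question of the design is which cells the beads recovered after injury and after 4-OI. Neutrophil-like cells, short-lived granulocytes that enter injured tissue from blood, rose from 4.19% ± 1.77 of kept cells in Sham to 18.4% ± 7.96 in vehicle (SD, n = 2 libraries per group), a 4.40-fold change (log2 2.14 ± 0.56 SE, adjusted p = 0.0425). Monocyte/macrophage-like cells rose from 1.42% ± 0.0908 to 4.58% ± 1.09 (SD, n = 2), a 3.23-fold change (log2 1.69 ± 0.39 SE, adjusted p = 0.0425). Microglia-like cells, the resident macrophages of brain tissue, made up 83.9% ± 3.87 in Sham and 69.0% ± 7.33 in vehicle, a difference that did not pass the test (adjusted p = 0.520). With 4-OI, neutrophil-like cells made up 29.6% ± 11.1, microglia-like cells 59.3% ± 7.84 and monocyte/macrophage-like cells 3.91% ± 1.53. Against vehicle these were folds of 1.60, 0.859 and 0.853, and none passed (edgeR adjusted p = 0.588, 0.592 and 0.705). The bead sort sets which cells enter, so these are shares of sorted cells and not of the tissue. Simulation at a preset spread, not that seen here, recovered a 2-fold change in 5 of 20 sets and a 4-fold in 19. The rise of monocyte/macrophage-like cells lost its call without vehicle library 1 or 2 (adjusted p = 0.130 and 0.237, range over its alternatives 0.0180 to 0.237), with the replicate block (0.0795) and with TMM over classes (0.0935). That of neutrophil-like cells lost it without vehicle library 1 or 2 or 4-OI library 1 or 2 (adjusted p = 0.130, 0.237, 0.0659 and 0.0659, range 0.0138 to 0.237). It also lost it with only the 2 groups compared (0.0659), the replicate block (0.0795), no doublet removal (0.0503) and TMM (0.111).

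**Figure D1:**
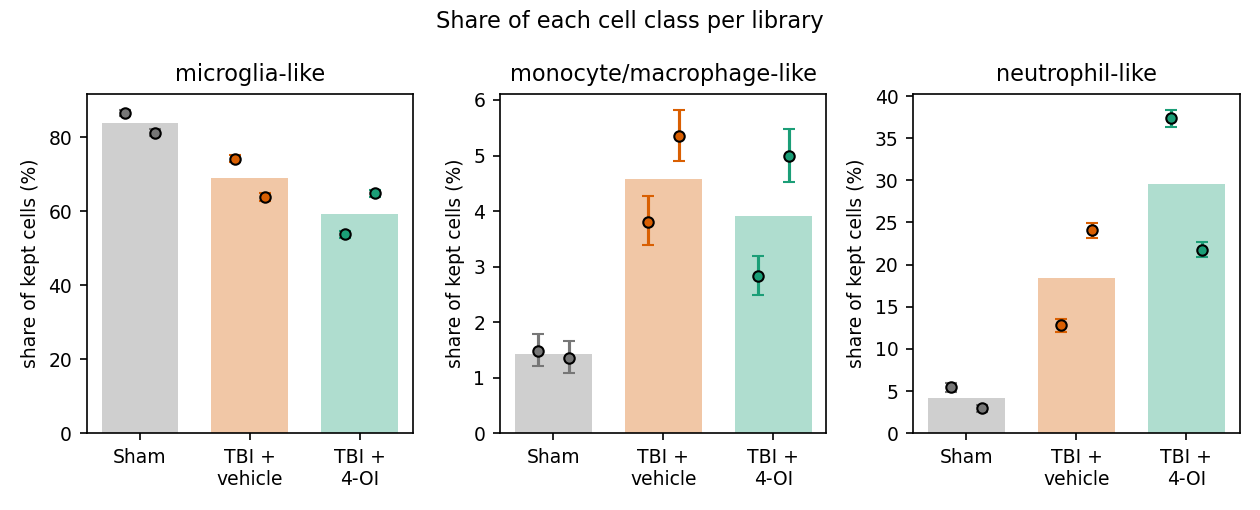
Share of kept cells (%) in each cell class by group. Bars are group means, points are single libraries with exact 95% binomial intervals, and the neutrophil-like mean runs from 4.19% in Sham to 18.4% in vehicle and 29.6% with 4-OI.

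The comparison of vehicle with Sham asks what the impact does to each cell class. In microglia-like cells Spp1, the gene of the secreted matrix protein osteopontin, rose from 1.38 ± 0.224 to 202 ± 17.3 CPM (counts scaled to the library total; SD, n = 2 libraries per group; log2 7.18 ± 0.17, adjusted p = 9.1e-11). Il1rn, the gene of the interleukin-1 receptor antagonist, rose from 0.226 ± 0.242 to 58.1 ± 19.5 CPM (log2 7.91 ± 0.38, adjusted p = 3.5e-08). Mmp12, the macrophage elastase gene, and Ptgs2, the gene of the prostaglandin enzyme COX-2, each had 1 Sham count, and their ratios of vehicle to Sham were 2719-fold, 95% counting interval 488 to 107440, and 1180-fold, 95% counting interval 211 to 46641. Hmox1, the heme-degrading enzyme gene, rose from 13.4 ± 1.68 to 72.3 ± 0.906 CPM (log2 2.43 ± 0.17, adjusted p = 5.2e-07). The cytokine gene Tnf rose by log2 2.26 ± 0.12, adjusted p = 6.1e-08. Among the largest falls were Adcy8, an adenylyl cyclase gene (22.3 ± 1.68 to 5.88 ± 1.01 CPM, log2 -1.93 ± 0.13, adjusted p = 5.7e-07), D7Ertd443e (log2 -1.88 ± 0.20), Tnfrsf17 (-1.65 ± 0.14) and Upk1b (-1.64 ± 0.13). Acod1, the gene of the enzyme that makes itaconate, had 1 Sham count and a ratio of 109.7-fold, 95% counting interval 19.3 to 4370. Il1b, the interleukin-1 beta gene, rose by log2 3.54 ± 0.33, adjusted p = 6.0e-06. Without Sham library 1 or 2 the change of Il1rn was log2 9.87 and 7.17. Without cluster 7, a setting chosen after seeing the data, Il1rn, Spp1 and Hmox1 stood at 5.24, 5.65 and 1.18. For Acod1 and Il1b microglia-like cells held under 10% of the CPM of another class, a level that free RNA alone can give. Gclm, a glutathione synthesis gene, rose by 0.29 ± 0.08 (adjusted p = 0.0110), a call that ended without Sham library 1 or 2 (adjusted p = 0.0815 and 0.0526, range over its alternatives 0.00864 to 0.526).

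Gene lists fixed in advance put these changes in groups. Values in parentheses after a gene are log2 fold changes ± SE, and counts adjusted over the list alone are given where they differ. Among NF-kB and inflammatory cytokine genes 17 of 24 rose and 1 fell, including the chemokine genes Ccl7 (6.76 ± 0.21) and Ccl2 (5.33 ± 0.24), with adjusted p = 1.7e-36, or 0.0228 with an estimated correlation. In the disease-associated microglia list 15 of 23 rose and 3 fell (15 and 4 over the list alone), with adjusted p = 1.6e-23, or 0.0239 with an estimated correlation. They included Spp1, the inhibitory receptor gene Lilrb4a (5.71 ± 0.17) and the fatty acid binding protein gene Fabp5 (4.18 ± 0.21). Of alternative activation and repair genes 12 of 16 rose and 1 fell, including Il1rn and the scavenger receptor genes Msr1 (5.80 ± 0.18) and Cd36 (4.92 ± 0.26), with adjusted p = 2.1e-24, or 0.0306 with an estimated correlation. Targets of NRF2, the transcription factor of the oxidant response, moved up: 19 of 24 rose, among them Srxn1 (3.42 ± 0.27) and Hmox1, with adjusted p = 8.2e-13, or 0.0326 with an estimated correlation. Of the genes of the ATF4 stress response 13 of 16 rose (15 over the list alone), among them Gdf15 (3.94 ± 0.24) and Psat1 (1.53 ± 0.13), with adjusted p = 1.1e-08, or 0.0532 with an estimated correlation. Glycolysis and hypoxia genes followed, as 20 of 25 rose and 2 fell (21 and 2 over the list alone), with adjusted p = 8.2e-19, or 0.0532 with an estimated correlation. Among them Adm, the gene of the vasodilator peptide adrenomedullin, was at least 15-fold higher than a Sham group at 0 counts. Of oxidative phosphorylation genes 20 of 28 rose and 0 fell (21 and 1 over the list alone), including the respiratory chain genes Cycs (0.99 ± 0.08) and Uqcrq (0.72 ± 0.07), with adjusted p = 6.6e-07, or 0.270 with an estimated correlation. Interferon response genes had 16 of 27 rise and 1 fall (16 and 2 over the list alone), including Cxcl10 (2.15 ± 0.32) and Ifi204 (1.92 ± 0.18), with adjusted p = 8.0e-05, or 0.376 with an estimated correlation. Immediate early and dissociation stress genes had 16 of 22 rise and 1 fall, with adjusted p = 6.6e-14, or 0.0707 with an estimated correlation. Among them were the heat shock genes Hspa1b (4.83 ± 0.28) and Hspa1a (4.58 ± 0.35), a near-identical pair that can share reads. Homeostatic microglia genes went down, as 13 of 19 fell (15 over the list alone), with adjusted p = 6.4e-10, or 0.205 with an estimated correlation. Among these were the sugar transporter gene Slc2a5 (-1.07 ± 0.08), the lipid receptor gene Gpr34 (-0.93 ± 0.11) and the purine receptor gene P2ry12 (-0.81 ± 0.10). Cholesterol efflux and lipid loading genes had 6 of 12 rise and 1 fall, including Fabp5 and Lpl (3.65 ± 0.11), with adjusted p = 4.6e-09, or 0.101 with an estimated correlation. Cell cycle genes had 7 of 19 rise and 2 fall, with the replication genes Mcm5 (1.74 ± 0.21) and Mcm2 (1.56 ± 0.18) and adjusted p = 0.00583, or 0.341 with an estimated correlation. Neutrophil activation genes, a list that shares cytokine genes with the NF-kB list, had 16 of 19 rise (17 over the list alone), with adjusted p = 2.4e-30, or 0.0228 with an estimated correlation. Markers of other cells moved with injury as well: of neutrophil markers 11 of 15 rose and 1 fell, with adjusted p = 8.5e-04, or 0.411 with an estimated correlation. Of neutrophil granule genes 7 of 13 rose, with adjusted p = 9.4e-04, or 0.376 with an estimated correlation. Of monocyte/macrophage markers 6 of 10 rose and 1 fell, with adjusted p = 0.00213, or 0.270 with an estimated correlation. Of mitochondrially encoded genes, a sign of RNA quality, 10 of 11 rose, with adjusted p = 1.0e-04, or 0.270 with an estimated correlation. No call was made (genes that rose and fell of those tested, then adjusted over the list alone) for inflammasome and pyroptosis (3 and 4 of 13, or 4 and 5, adjusted p = 0.943), antigen presentation (3 and 3 of 16, adjusted p = 0.448) and phagocyte oxidase (2 and 2 of 7, or 4 and 2, adjusted p = 0.171). Nor was one made for lysosome and phagocytosis (10 and 3 of 23, or 10 and 6, adjusted p = 0.0912), cholesterol synthesis (6 and 0 of 16, adjusted p = 0.0984), astrocyte markers (0 and 1 of 6, adjusted p = 0.830) and erythroid markers (1 and 0 of 5, or 0 and 0, adjusted p = 0.619). Across all 14451 genes tested in microglia-like cells, 2989 rose and 2581 fell, of which 843 and 204 changed at least 2-fold. The groups were apart in 71.5% of genes where chance gives 33.3%. Sham microglia-like cells lay mostly in clusters 0 and 1 and those after injury also in clusters 2, 4 and 7. Ccl7 stood at 6.09 and 7.81 and Cxcl10 at 1.47 and 3.30 without Sham library 1 or 2. Without cluster 7 Ccl7 stood at 4.47, Ccl2 at 3.63, Lilrb4a at 3.23, Fabp5 at 1.84, Msr1 at 4.13, Cd36 at 1.86, Srxn1 at 1.80, Gdf15 at 2.66 and Lpl at 1.94. Of the calls 287 were of genes under the preset limit for free RNA. Without Sham library 1 or vehicle library 1 the genes that fell numbered 1715 and 1626, and a fold threshold of 1.2 left 1807 rising and 983 falling.

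In monocyte/macrophage-like cells Ccl7, a chemokine gene for monocytes, had 0 Sham counts and was at least 51.6-fold higher in vehicle, against 3 counts over the Sham group (n = 2 libraries per group). On the same floor Hcar2, a receptor gene for the ketone body hydroxybutyrate, Cd38, an NAD-consuming enzyme gene, and Rhov, a small GTPase gene, were at least 21.4-fold higher, at least 21.2-fold higher and at least 17.5-fold higher. Il1b rose from 142 ± 52.1 to 1135 ± 100.1 CPM (SD; log2 2.98 ± 0.22, adjusted p = 3.4e-07). Hmox1 rose by log2 2.13 ± 0.29, adjusted p = 8.7e-05, and Gclm by log2 2.26 ± 0.35, adjusted p = 3.1e-04. Acod1 had 1 Sham count and a ratio of 103-fold, 95% counting interval 18.3 to 4058. Tnf did not pass (log2 0.56 ± 0.41, adjusted p = 0.386). Clec2i, a gene of a lectin that natural killer receptors bind, fell from 137 ± 23.0 to 17.6 ± 3.31 CPM (log2 -2.94 ± 0.21, adjusted p = 3.1e-07). Klrb1f, Ccdc192 and Fabp4 fell by 3.16 ± 0.58, 3.02 ± 0.37 and 2.72 ± 0.48 on the log2 scale. The call for Fabp4, a lipid chaperone gene, ended without Sham library 2 (log2 -1.25, adjusted p = 0.102, range over its alternatives 1.8e-25 to 0.102), and without Sham library 1 it stood at -3.45. Hmox1 stood at 3.31 and Gclm at 2.97 without Sham library 1, and Klrb1f at -4.02 without vehicle library 2.

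By list, glycolysis and hypoxia genes stood out in this class, as 24 of 24 rose, with adjusted p = 3.5e-49, or 0.0532 with an estimated correlation. They included the growth factor gene Vegfa (4.74 ± 0.43), the oxygen sensor gene Egln3 (4.42 ± 0.39), the glycolytic enzyme gene Pfkl (3.26 ± 0.33) and the cytokine gene Mif (3.14 ± 0.25). Alternative activation and repair genes had 11 of 16 rise and 0 fall (12 and 1 over the list alone), with adjusted p = 7.5e-24, or 0.0239 with an estimated correlation. They included the arginase gene Arg1 (5.39 ± 0.40), the matrix gene Thbs1 (5.11 ± 0.25) and the transglutaminase gene Tgm2 (3.85 ± 0.28). Disease-associated microglia genes had 12 of 21 rise, including Spp1 (7.88 ± 0.66) and Cd63 (2.95 ± 0.27), with adjusted p = 6.1e-12, or 0.0326 with an estimated correlation. Of NF-kB and inflammatory cytokine genes 15 of 26 rose and 0 fell (15 and 2 over the list alone), with adjusted p = 3.8e-18, or 0.0532 with an estimated correlation. Among them Ccl2 rose (6.28 ± 0.37), and Ccl4, a chemokine gene with 3 Sham counts, had a ratio of 83.0-fold, 95% counting interval 28.3 to 403. Of NRF2 targets 14 of 22 rose and 3 fell (14 and 4 over the list alone), including the cystine transporter gene Slc7a11 (3.59 ± 0.28) and the ferritin gene Fth1 (2.96 ± 0.17), with adjusted p = 1.9e-07, or 0.101 with an estimated correlation. ATF4 stress genes had 7 of 15 rise (11 over the list alone), including the amino acid transporter gene Slc3a2 (2.24 ± 0.19), with adjusted p = 2.2e-04, or 0.121 with an estimated correlation. Neutrophil activation genes had 16 of 20 rise and 0 fall (16 and 1 over the list alone), including Cxcl3 (6.30 ± 0.35) and Cxcl2 (4.45 ± 0.26), with adjusted p = 2.1e-33, or 0.0228 with an estimated correlation. Lysosome genes had 8 of 23 rise and 1 fall (8 and 3 over the list alone), including the cathepsin gene Ctsl (2.60 ± 0.16) and the Fc receptor gene Fcgr1 (1.81 ± 0.18), with adjusted p = 6.7e-04, or 0.121 with an estimated correlation. Cholesterol efflux and lipid loading genes had 7 of 13 rise and 1 fall, with adjusted p = 2.4e-04, or 0.101 with an estimated correlation. Examples are the lipid droplet gene Hilpda (4.60 ± 0.41) and the exporter gene Abca1 (2.65 ± 0.22). Homeostatic microglia genes moved down, as 1 of 19 rose and 6 fell (1 and 12 over the list alone), with the chemokine receptor gene Cx3cr1 (-1.22 ± 0.19) and adjusted p = 0.00139, or 0.413 with an estimated correlation. Neutrophil markers rose here too, as 14 of 15 rose, including Lcn2 (4.69 ± 0.58) and S100a8 (4.20 ± 0.35), with adjusted p = 6.3e-17, or 0.108 with an estimated correlation. Of granule genes 9 of 15 rose and 2 fell (10 and 2 over the list alone), with adjusted p = 1.1e-05, or 0.143 with an estimated correlation. Of mitochondrially encoded genes 9 of 11 rose (10 over the list alone), with adjusted p = 3.6e-05, or 0.201 with an estimated correlation. In monocyte/macrophage-like cells no list call was made for interferon response (5 and 2 of 27, adjusted p = 0.943), inflammasome (4 and 3 of 13, adjusted p = 0.336), oxidative phosphorylation (5 and 0 of 28, adjusted p = 0.162) and antigen presentation (5 and 5 of 16, or 5 and 7, adjusted p = 0.923). The same held for phagocyte oxidase (1 and 1 of 7, adjusted p = 0.619), cholesterol synthesis (1 and 0 of 15, or 0 and 0, adjusted p = 0.428), cell cycle (0 and 1 of 17, or 0 and 0, adjusted p = 0.619) and immediate early genes (8 and 3 of 22, or 9 and 3, adjusted p = 0.0743). Cluster 20, where Cx3cr1 had 542 CPM against 202 in cluster 9, held a larger part of this class in Sham than in vehicle, though cluster 9 held most of it in each. Leaving out Sham library 1 put Slc7a11 at log2 4.89, Ccl2 at 7.06, Egln3 at 5.13, Mif at 4.05, Spp1 at 8.77, Thbs1 at 5.99 and S100a8 at 4.86. Arg1, Hilpda and Cxcl3 stood at 9.49, 6.49 and 7.89 without Sham library 1 and at 4.54, 3.91 and 5.67 without Sham library 2. Vegfa had 0 counts in Sham library 2 and stood at 3.87 without it. Pfkl stood at 3.96 and Cxcl2 at 5.15 without Sham library 2, and Lcn2 at 3.87 without vehicle library 1. Of 10148 genes tested, 1264 rose and 742 fell, 829 and 354 of them at least 2-fold. Of these calls 29 were of genes within reach of free RNA, and the groups were apart in 59.0% of genes. Without Sham library 2 the genes that rose numbered 829, and without Sham library 1 or 2 those that fell numbered 351 and 408. With equal cell numbers in every library, a setting chosen after seeing the data, 825 rose and 445 fell, and DESeq2 called 441 falls.

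In neutrophil-like cells Cxcr1, a chemokine receptor gene of neutrophils, and Gpnmb, a glycoprotein gene of lipid-laden phagocytes, had 0 Sham counts and were at least 39.6-fold higher and at least 18.6-fold higher against 3 counts over the group (n = 2 libraries per group). Acod1 rose from 12.1 ± 14.2 to 439.8 ± 98.5 CPM (SD; log2 5.02 ± 0.50, adjusted p = 6.4e-05). Hmox1 rose from 21.8 ± 6.90 to 251 ± 6.70 CPM (log2 3.48 ± 0.25, adjusted p = 1.2e-05) and Il1b from 181 ± 68.1 to 1320 ± 64.5 CPM (log2 2.85 ± 0.29, adjusted p = 7.4e-05). Stfa2, a cysteine protease inhibitor gene of a family with near-identical copies, rose by log2 8.02 ± 1.42, adjusted p = 0.00218. Gpc3, a cell surface proteoglycan gene with 2 Sham counts, had a ratio of 262-fold, 95% counting interval 72.4 to 2164. Sntb1, a gene of a membrane scaffold protein, fell from 82.5 ± 11.2 to 2.65 ± 0.246 CPM (log2 -4.94 ± 0.28, adjusted p = 5.7e-06). Itga8 and Adgrl3 fell by 4.60 ± 0.47 and 4.02 ± 0.48 on the log2 scale. Gclm rose by log2 2.01 ± 0.24, adjusted p = 1.8e-04. Tex15 fell by 3.71 ± 0.28 and lost its call without clusters 10 and 21, at log2 -1.91, adjusted p = 0.343 (range 3.7e-32 to 0.343). In that fit, chosen after seeing the data, Acod1 stood at 3.03, Il1b at 0.79, Hmox1 at 2.42, Gclm at 2.63, Sntb1 at -6.32 and Itga8 at -6.10. Acod1 stood at 7.83 and 4.31 without Sham library 1 or 2, and Itga8 at -3.90 without Sham library 1. Stfa2 had 0 counts in Sham library 2 and stood at 7.29 without it, and at 5.28 and 8.95 without vehicle library 1 or 2. Nqo1, a quinone reductase gene, had 1 Sham count and a ratio of 4.21-fold, 95% counting interval 0.665 to 176, and did not pass (adjusted p = 0.301; it was below the low-count filter in the other classes). Tnf rose by log2 1.04 ± 0.33, adjusted p = 0.0399, a call lost without Sham library 1 or 2, vehicle library 1 or clusters 10 and 21 (adjusted p = 0.109, 0.202, 0.129 and 0.199, range over its alternatives 1.2e-04 to 0.202). Most neutrophil-like cells of the Sham libraries lay in clusters 10 and 21, which are marked by granule genes, and most of those of the vehicle and 4-OI libraries in clusters 3, 6 and 8.

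In neutrophil-like cells granule and maturation genes moved down, as 1 of 15 rose and 9 fell (1 and 10 over the list alone), with adjusted p = 1.4e-09, or 0.121 with an estimated correlation. Among them the antimicrobial protein genes Camp (-2.79 ± 0.37) and Ltf (-2.54 ± 0.25) lost their calls without clusters 10 and 21. Camp then stood at log2 -0.25, adjusted p = 0.860 (range over its alternatives 2.8e-23 to 0.860), and Ltf at 0.60, adjusted p = 0.731 (range 1.2e-48 to 0.731). Glycolysis and hypoxia genes went up, as 23 of 24 rose, including Mif (4.80 ± 0.26), Egln3 (4.38 ± 0.29) and Bnip3 (4.31 ± 0.27), the last a mitophagy gene, with adjusted p = 1.0e-33, or 0.101 with an estimated correlation. NF-kB and inflammatory cytokine genes had 21 of 23 rise, including the nitric oxide synthase gene Nos2 (6.12 ± 0.31), with adjusted p = 2.0e-22, or 0.0408 with an estimated correlation. Neutrophil activation genes had 17 of 20 rise and 1 fall, including the chemokine genes Ccl3 (5.62 ± 0.51) and Cxcl2 (5.16 ± 0.54), with adjusted p = 2.1e-18, or 0.103 with an estimated correlation. Disease-associated microglia genes, a list that holds lysosome and lipid genes shared by phagocytes, had 15 of 20 rise (17 over the list alone), including Spp1 (4.33 ± 0.52) and Csf1 (3.86 ± 0.33), with adjusted p = 6.1e-12, or 0.0326 with an estimated correlation. Interferon response genes had 20 of 26 rise and 2 fall (23 and 2 over the list alone), with the antiviral gene Ifit1 (2.64 ± 0.28) and adjusted p = 1.3e-07, or 0.248 with an estimated correlation. NRF2 targets had 10 of 23 rise and 3 fall, including Fth1 (4.31 ± 0.40) and Hmox1, with adjusted p = 4.3e-04, or 0.257 with an estimated correlation. ATF4 stress genes had 8 of 16 rise and 0 fall (11 and 2 over the list alone), including Ddit4 (4.40 ± 0.38) and Cebpb (3.35 ± 0.28), with adjusted p = 2.1e-05, or 0.121 with an estimated correlation. Inflammasome genes had 8 of 13 rise, with adjusted p = 5.1e-04, or 0.121 with an estimated correlation. Alternative activation genes had 9 of 15 rise and 1 fall (10 and 1 over the list alone), including Tgm2 (4.74 ± 0.30) and Socs3 (3.79 ± 0.25), with adjusted p = 1.3e-07, or 0.0754 with an estimated correlation. Lysosome genes had 12 of 21 rise and 1 fall, with Ctsb (2.46 ± 0.29) and Ctsl (2.30 ± 0.26) and adjusted p = 1.4e-05, or 0.201 with an estimated correlation. Cholesterol efflux and lipid loading genes moved up as well, as 8 of 10 rose (9 over the list alone), with Hilpda (5.62 ± 0.47) and Abca1 (4.02 ± 0.29) and adjusted p = 6.3e-10, or 0.101 with an estimated correlation. Immediate early genes had 12 of 20 rise (14 over the list alone), including the transcription factor genes Atf3 (4.01 ± 0.38) and Jun (3.18 ± 0.31), with adjusted p = 9.1e-06, or 0.210 with an estimated correlation. Mitochondrially encoded genes had 9 of 11 rise (10 over the list alone), with adjusted p = 9.3e-04, or 0.376 with an estimated correlation. Down with the granule genes were oxidative phosphorylation genes, of which 6 of 28 fell, with adjusted p = 0.00851, or 0.548 with an estimated correlation. Among them the respiratory chain gene Cox5a (-0.85 ± 0.17) lost its call without clusters 10 and 21 (log2 -0.34, adjusted p = 0.445, range 3.0e-04 to 0.445). Cell cycle genes had 5 of 23 fall, with adjusted p = 6.7e-04, or 0.516 with an estimated correlation. Among them the topoisomerase gene Top2a (-1.60 ± 0.48) lost its call without Sham library 2 or vehicle library 1 (adjusted p = 0.391 and 0.102, range 5.6e-10 to 0.391). It stood at -0.62 without Sham library 2 and -2.35 without vehicle library 2. Phagocyte oxidase genes had 3 of 7 fall, with the catalytic subunit gene Cybb (-2.59 ± 0.21) and adjusted p = 6.7e-04, or 0.341 with an estimated correlation. In neutrophil-like cells no list call was made for antigen presentation (2 and 6 of 15, or 2 and 7, adjusted p = 0.255), homeostatic microglia (2 and 0 of 19, or 1 and 0, adjusted p = 0.698) and cholesterol synthesis (1 and 0 of 14, or 0 and 0, adjusted p = 0.828). Without clusters 10 and 21 calls also ended for Nlrp3, Il18 and Ninj1 of the inflammasome list and Isg15, Oasl1 and Cxcl10 of the interferon list. They ended as well for Srxn1, Atf5, Ccl7, Selplg, Hbegf, Arg1, Ncf1, Atp5h and Mki67. Other named genes kept their calls in that fit at smaller changes, such as Nos2 (4.07), Spp1 (2.59), Csf1 (2.04) and Ifit1 (1.02). Ddit4, Spp1, Csf1, Hilpda and Cxcl2 stood at 6.25, 6.18, 4.75, 7.24 and 6.24 without Sham library 1, and Spp1 and Hilpda at 3.65 and 5.03 without Sham library 2. Of 10853 genes tested, 1773 rose and 1213 fell, 1322 and 853 of them at least 2-fold. Of these calls 58 were of genes within reach of free RNA, and the groups were apart in 63.4% of genes. Without Sham library 1 or vehicle library 2 the genes that fell numbered 708 and 731, and without clusters 10 and 21, a setting chosen after seeing the data, 983 rose and 495 fell. With equal cell numbers 958 rose and 664 fell.

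**Figure D2:**
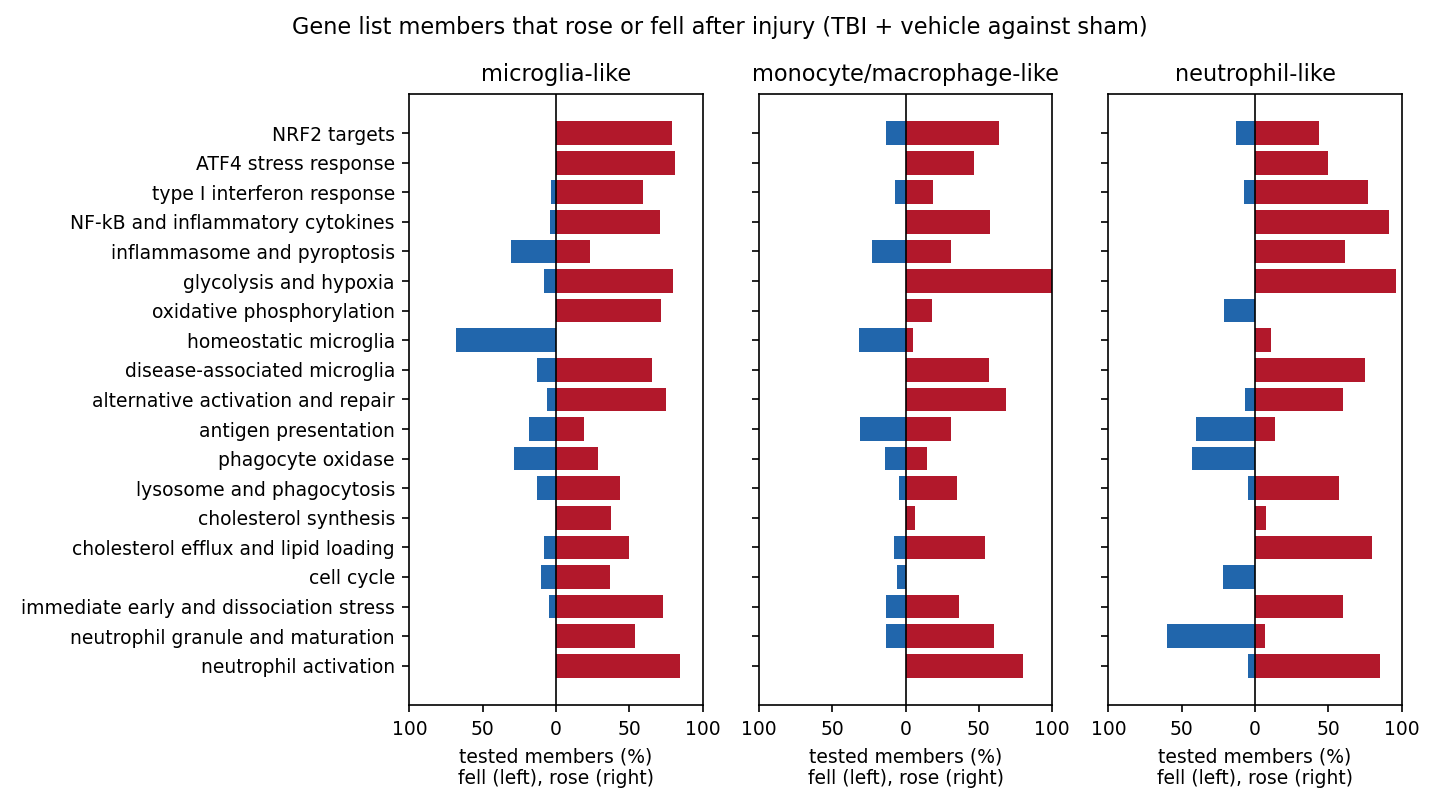
Percent of tested list members that fell (left of 0) or rose (right of 0) in vehicle against Sham, for gene lists fixed in advance and in the 3 cell classes. Each bar is 1 list in 1 class, and glycolysis and hypoxia genes rose in 24 of 24 members in monocyte/macrophage-like cells.

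The comparison of 4-OI with vehicle asks what the drug changes in injured animals. In microglia-like cells Fabp5, a fatty acid binding protein gene that had risen after injury (log2 4.18 ± 0.21), fell from 45.3 ± 6.93 CPM in vehicle to 20.1 ± 5.78 with 4-OI (SD, n = 2 libraries per group; log2 -1.17 ± 0.16, adjusted p = 0.0279). Its Sham level was 2.49 ± 0.0126. Ccl7, a monocyte chemokine gene, fell from 68.8 ± 5.83 to 39.5 ± 3.25 CPM (log2 -0.80 ± 0.12, adjusted p = 0.0318). Mrc1, the mannose receptor gene, fell from 31.0 ± 0.472 to 19.3 ± 0.164 CPM (log2 -0.68 ± 0.09, adjusted p = 0.0279). The heat shock gene Hspa1b rose from 13.5 ± 3.91 to 29.0 ± 0.838 CPM (log2 1.08 ± 0.15, adjusted p = 0.0279). Hsph1, a cochaperone gene, rose from 28.2 ± 2.91 to 43.6 ± 1.12 CPM (log2 0.62 ± 0.09, adjusted p = 0.0318). Egr1, an immediate early transcription factor gene, rose from 169 ± 9.93 to 257 ± 17.6 CPM (log2 0.60 ± 0.07, adjusted p = 0.0279). The other calls were falls of Cemip, a hyaluronan-degrading protein gene at 1.69 and 2.12 CPM in the vehicle libraries (log2 -4.95 ± 0.68), and Cd52, a leukocyte surface gene under the preset limit for free RNA (log2 -0.54 ± 0.08). Both are named here after their values were seen. None of the genes named in advance for the itaconate, NRF2 and cytokine responses passed in this class: Acod1 at log2 0.16 ± 0.28, adjusted p = 0.904, Hmox1 at log2 0.04 ± 0.14, adjusted p = 0.951, Gclm at log2 -0.18 ± 0.08, adjusted p = 0.529, Il1b at log2 0.36 ± 0.23, adjusted p = 0.697 and Tnf at log2 -0.12 ± 0.10, adjusted p = 0.780. Of 14451 genes tested 3 rose and 5 fell, 1 and 2 of them at least 2-fold. An unadjusted p under 0.05 was found for 1291 where 723 are due by chance. The groups were apart in 38.0% of genes where chance gives 33.3%. Calls ended for Fabp5, Ccl7, Mrc1, Hspa1b, Hsph1 and Egr1 without 4-OI library 1, and for these but Fabp5 without 4-OI library 2. Without vehicle library 1 they ended for Fabp5, Ccl7, Mrc1 and Egr1. Over all alternatives the adjusted p ran from 2.0e-25 to 0.468 for Fabp5, 2.0e-15 to 0.442 for Ccl7, 1.9e-07 to 0.431 for Mrc1, 1.1e-17 to 0.292 for Hspa1b, 9.9e-08 to 0.299 for Hsph1 and 1.9e-11 to 0.185 for Egr1. The counts of rises and falls became 0 and 0 without 4-OI library 1 (edgeR), 11 and 40 without vehicle library 2, 4 and 2 without vehicle library 1, and 5 and 49 with DESeq2. Without cluster 7, the microglia cluster with the lowest marker score, a setting chosen after seeing the data, 1 rose and 0 fell (edgeR), and Fabp5 stood at log2 -0.46, adjusted p = 0.468.

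Camera called 33 of the 65 list tests of this contrast over the 3 classes, fry 1, and camera with an estimated correlation 0 (lowest adjusted p = 0.176). Camera placed immediate early and dissociation stress genes higher in microglia-like cells, while 2 of 22 rose (11 over the list alone) and the median change was 0.25 (adjusted p = 1.6e-20, or 0.180 with an estimated correlation). It placed disease-associated microglia genes lower (median -0.25), while 0 of 23 rose and 1 fell (1 and 11 over the list alone), with adjusted p = 8.5e-16, or 0.176 with an estimated correlation. Lysosome genes were placed lower (median -0.17), while 0 of 23 passed (1 fell over the list alone), with adjusted p = 1.2e-09, or 0.180 with an estimated correlation, and fry gave adjusted p = 0.0162. The scavenger receptor gene Cd36 stood at -0.80 ± 0.16 without passing. Glycolysis and hypoxia genes were placed lower (median -0.15), while 0 of 25 passed (6 fell over the list alone), with adjusted p = 1.6e-07, or 0.251 with an estimated correlation. Oxidative phosphorylation genes were placed lower (median -0.13), while 0 of 28 passed (1 fell over the list alone), with adjusted p = 1.6e-06, or 0.417 with an estimated correlation. Mitochondrially encoded genes were also lower (median -0.29), while 0 of 11 passed (4 fell over the list alone), with adjusted p = 1.7e-07, or 0.415 with an estimated correlation. Cholesterol efflux and lipid loading genes were also placed lower (median -0.20), while 1 of 12 fell (5 over the list alone), with adjusted p = 2.9e-06, or 0.307 with an estimated correlation. Alternative activation genes were placed lower (median -0.12), while 0 of 16 rose and 1 fell (1 and 6 over the list alone), with adjusted p = 2.1e-05, or 0.251 with an estimated correlation. The placement was upward for ATF4 stress genes, of which 0 of 16 passed (1 rose over the list alone), with adjusted p = 8.7e-04, or 0.251 with an estimated correlation. It was downward for antigen presentation genes (median -0.15), of which 0 of 16 passed, also over the list alone, with adjusted p = 0.00119, or 0.251 with an estimated correlation. Erythroid markers were placed lower (median -0.52), while 0 of 5 passed, also over the list alone, with adjusted p = 0.0147, or 0.526 with an estimated correlation. Interferon response genes were placed lower (median -0.08), while 0 of 27 passed, also over the list alone, with adjusted p = 0.0387, or 0.759 with an estimated correlation. No call was made in microglia-like cells for NRF2 targets (0 and 0 of 24, or 0 and 1, adjusted p = 0.293), NF-kB and inflammatory cytokines (0 and 1 of 24, or 1 and 2, adjusted p = 0.647), inflammasome (0 and 0 of 13, adjusted p = 0.596) and homeostatic microglia (0 and 0 of 19, adjusted p = 0.102). None was made for phagocyte oxidase (0 and 0 of 7, or 0 and 1, adjusted p = 0.227), cholesterol synthesis (0 and 0 of 16, adjusted p = 0.825), cell cycle (0 and 0 of 19, adjusted p = 0.876) and neutrophil granule genes (0 and 0 of 13, or 0 and 1, adjusted p = 0.272). Further lists without a call were neutrophil activation (0 and 0 of 19, adjusted p = 0.150), astrocyte markers (0 and 0 of 6, adjusted p = 0.680), neutrophil markers (0 and 0 of 15, adjusted p = 0.119) and monocyte/macrophage markers (0 and 0 of 10, adjusted p = 0.0670).

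In monocyte/macrophage-like cells Inhba, the gene of the activin A subunit, fell with 4-OI from 131 ± 4.45 to 57.3 ± 19.5 CPM (SD, n = 2 libraries per group; log2 -1.16 ± 0.18, adjusted p = 0.0357). Ms4a7, a macrophage membrane gene, fell from 44.2 ± 1.94 to 19.1 ± 2.21 CPM (log2 -1.23 ± 0.20, adjusted p = 0.0357). As for Mrc1, RNA of cluster 23 (494 CPM) is not excluded. Csta2, a cysteine protease inhibitor gene of a family with near-identical copies, fell from 37.3 ± 1.48 to 11.4 ± 6.14 CPM (log2 -1.80 ± 0.29, adjusted p = 0.0357). The neutrophil granule gene Ngp (log2 -3.19 ± 0.27, adjusted p = 9.0e-05) and the chemokine gene Ccl12 (log2 -0.98 ± 0.13, adjusted p = 0.0123) fell at levels under the preset limit for free RNA. So did Cstdc5 (log2 -4.79 ± 0.68), which is named here after its values were seen. All 6 genes that fell here had risen after injury, a contrast that shares the vehicle libraries. After injury Inhba stood at log2 7.08 ± 0.57 and Ms4a7 at 1.79 ± 0.32. None of the genes named in advance passed: Acod1 at log2 0.08 ± 0.19, adjusted p = 1, Hmox1 at log2 -0.34 ± 0.22, adjusted p = 0.935, Gclm at log2 -0.40 ± 0.19, adjusted p = 0.881, Il1b at log2 -0.37 ± 0.18, adjusted p = 0.863 and Tnf at log2 0.17 ± 0.27, adjusted p = 0.985. Of 10148 genes tested in this class edgeR called 0 rises and 6 falls and DESeq2 0 and 3, while 591 genes had an unadjusted p under 0.05 where 507 are due by chance. The groups were apart in 35.3% of genes. Without 4-OI library 1 Csta2 stood at -2.40. Calls ended for Csta2 and Ms4a7 without 4-OI library 2, and for these and Inhba without Sham library 1 or 2. Over all alternatives the adjusted p ran from 1.7e-09 to 1 for Csta2, 1.5e-05 to 1 for Ms4a7 and 5.5e-10 to 0.907 for Inhba. The falls numbered 3 without Sham library 1 or 2, 15 and 10 without 4-OI library 1 or 2, and 21 and 46 without vehicle library 1 or 2, where the rises were 0, 0, 4, 9, 11 and 4. The call for Ngp ended without doublet removal (log2 -0.92, adjusted p = 0.592, range 7.8e-37 to 0.592), and that for Ccl12 with looser cells, stricter cells, resolution 0.5 and equal cell numbers (adjusted p = 0.220, 0.267, 0.368 and 0.762, lowest over its alternatives 2.3e-08).

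By list in this class, neutrophil granule genes were placed lower (median -0.80), while 1 of 15 fell (7 over the list alone), with adjusted p = 1.3e-12, or 0.251 with an estimated correlation. Neutrophil markers were placed lower (median -0.70), while 0 of 15 rose and 1 fell (2 and 9 over the list alone), with adjusted p = 2.5e-05, or 0.417 with an estimated correlation. Cell cycle genes were placed lower (median -0.79), while 0 of 17 passed (4 fell over the list alone), with adjusted p = 6.6e-09, or 0.417 with an estimated correlation. The ubiquitin conjugase gene Ube2c stood at -1.66 ± 0.45 without passing. Homeostatic microglia genes were placed lower (median -0.47), while 0 of 19 passed (1 fell over the list alone), with adjusted p = 1.6e-07, or 0.417 with an estimated correlation. Their medians in T, B and NK-like cells were lower too (-1.17, -0.83 and -0.72), so free microglial RNA is not excluded. Also placed lower were cholesterol synthesis (median -0.34), glycolysis and hypoxia, and lysosome genes (median -0.09). Of these 0 of 15, 24 and 23 passed, also over the list alone. Camera gave adjusted p = 6.9e-06, 0.00489 and 0.00570, or 0.417, 0.587 and 0.307 with an estimated correlation. Disease-associated microglia genes had a median of -0.05, while 0 of 21 passed (1 rose and 2 fell over the list alone), with adjusted p = 0.0387, or 0.415 with an estimated correlation. The growth factor gene Csf1 stood at 1.12 ± 0.29 without passing. Upward were immediate early genes (median 0.20), of which 0 of 22 passed, also over the list alone, with adjusted p = 9.0e-05, or 0.417 with an estimated correlation. So were ATF4 stress genes, of which 0 of 15 passed, also over the list alone, with adjusted p = 0.0139, or 0.417 with an estimated correlation. Lists without a call in monocyte/macrophage-like cells were NRF2 targets (0 and 0 of 22, adjusted p = 0.647), interferon response (0 and 0 of 27, or 1 and 5, adjusted p = 0.0604), NF-kB and inflammatory cytokines (0 and 1 of 26, or 0 and 2, adjusted p = 0.925) and inflammasome (0 and 0 of 13, or 0 and 1, adjusted p = 0.596). They also included oxidative phosphorylation (0 and 0 of 28, adjusted p = 0.867), alternative activation (0 and 0 of 16, adjusted p = 0.867), antigen presentation (0 and 0 of 16, or 0 and 1, adjusted p = 0.129) and phagocyte oxidase (0 and 0 of 7, adjusted p = 0.876). The same was found for cholesterol efflux (0 and 0 of 13, or 1 and 1, adjusted p = 0.140), neutrophil activation (0 and 0 of 20, or 2 and 2, adjusted p = 0.825) and mitochondrially encoded genes (0 and 0 of 11, adjusted p = 0.0965).

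In neutrophil-like cells Prtn3, the gene of the granule serine protease proteinase 3, fell from 96.8 ± 84.4 CPM in vehicle to 5.54 ± 1.21 with 4-OI (SD, n = 2 libraries per group; log2 -4.10 ± 0.57, adjusted p = 0.0469). Fcnb, the gene of the granule lectin ficolin-B, fell from 55.4 ± 30.0 to 6.34 ± 0.454 CPM (log2 -3.15 ± 0.46, adjusted p = 0.0469). Dbi, an acyl-CoA binding protein gene, fell from 53.0 ± 0.0279 to 17.9 ± 2.46 CPM (log2 -1.58 ± 0.19, adjusted p = 0.0469). Tmem256 fell by 1.61 ± 0.23 and Fdps, a sterol synthesis gene, by 1.38 ± 0.23 on the log2 scale. Among the falls were 5 ribosomal protein genes, from -1.56 ± 0.21 for Rpsa to -1.05 ± 0.17 for Rpl15, whose pseudogenes can share reads. They are named here after their values were seen. Hbb-bt, a haemoglobin gene and erythroid marker, rose from 3.88 ± 3.39 to 53.1 ± 39.3 CPM (log2 3.61 ± 0.59, adjusted p = 0.0499). None of the genes named in advance passed here: Acod1 stood at log2 0.53 ± 0.36, adjusted p = 0.407, Hmox1 at log2 -0.11 ± 0.19, adjusted p = 0.767, Gclm at log2 -1.03 ± 0.21, adjusted p = 0.0573, Il1b at log2 0.51 ± 0.26, adjusted p = 0.285, Tnf at log2 0.46 ± 0.28, adjusted p = 0.345 and Nqo1 at log2 0.24 ± 0.64, adjusted p = 0.855. Of 10853 genes tested 2 rose and 19 fell, all with an adjusted p between 0.0469 and 0.0499. An unadjusted p under 0.05 was found for 2385 where 543 are due by chance. The groups were apart in 60.1% of genes. Calls ended for Prtn3, Fcnb, Dbi, Tmem256 and Fdps without 4-OI library 1 or 2. They ended for Hbb-bt without 4-OI library 2 or Sham library 1, and for Fdps without vehicle library 1. Prtn3 stood at -4.77 and -2.63 without vehicle library 1 or 2, Fcnb at -2.36 without vehicle library 2, and Hbb-bt at 4.26, 2.66 and 5.17 without 4-OI library 1, 4-OI library 2 or vehicle library 2. Without clusters 10 and 21 calls ended for Prtn3 (log2 -2.05), Dbi (-1.08), Tmem256 (-1.38) and Hbb-bt (3.09), at adjusted p = 0.0718, 0.148, 0.129 and 0.0587. With equal cell numbers they ended for Prtn3, Fcnb, Dbi and Tmem256 (adjusted p = 0.0627, 0.514, 0.0912 and 0.0951). Over all alternatives the adjusted p ran from 2.7e-54 to 0.168 for Prtn3, 1.0e-30 to 0.514 for Fcnb, 3.4e-09 to 0.484 for Dbi, 3.5e-09 to 0.433 for Tmem256, 2.2e-04 to 0.490 for Fdps and 1.2e-35 to 0.168 for Hbb-bt. Rises and falls numbered 1 and 0 without 4-OI library 1, 0 and 0 without 4-OI library 2, 7 and 85 without vehicle library 1, 85 and 134 without vehicle library 2, 59 and 127 without Sham library 1, and 63 and 151 without Sham library 2. They were 0 and 0 with RLE size factors or only the 2 groups compared in edgeR, and 166 and 171 with DESeq2.

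Cell cycle genes were placed lower by camera in neutrophil-like cells (median -1.88), while 0 of 23 passed (18 fell over the list alone), with adjusted p = 5.5e-12, or 0.417 with an estimated correlation. The nucleotide synthesis gene Rrm2 stood at log2 -3.25 ± 0.66, adjusted p = 0.0573. Granule and maturation genes were placed lower (median -0.96), while 0 of 15 passed (11 fell over the list alone), with adjusted p = 1.7e-11, or 0.251 with an estimated correlation. The granule gene Ngp stood at log2 -1.26 ± 0.31, adjusted p = 0.0742. Mitochondrially encoded genes were placed lower (median -0.87), while 0 of 11 passed (11 fell over the list alone), with adjusted p = 2.5e-08, or 0.417 with an estimated correlation. Oxidative phosphorylation genes were placed lower (median -0.45), while 0 of 28 passed (9 fell over the list alone), with adjusted p = 3.1e-06, or 0.505 with an estimated correlation. Cholesterol synthesis genes were placed lower here too (median -0.42), while 1 of 14 fell (4 over the list alone), with adjusted p = 0.00115, or 0.509 with an estimated correlation. Homeostatic microglia genes (median -0.52) had 0 of 19 pass, also over the list alone, with adjusted p = 0.0258, or 0.759 with an estimated correlation. Free microglial RNA is not excluded here either. Phagocyte oxidase genes (median -0.51) had 0 of 7 pass (3 fell over the list alone), with adjusted p = 0.0364, or 0.640 with an estimated correlation. Upward placements were those of immediate early genes (median 0.46), of which 0 of 20 passed (2 rose over the list alone), with adjusted p = 9.6e-05, or 0.417 with an estimated correlation. Also upward were neutrophil activation genes (median 0.44), of which 0 of 20 passed (3 rose over the list alone), with adjusted p = 3.9e-04, or 0.526 with an estimated correlation. Interferon response genes (median 0.46) had 0 of 26 pass (3 rose and 1 fell over the list alone), with adjusted p = 5.1e-04, or 0.526 with an estimated correlation. NF-kB and inflammatory cytokine genes (median 0.51) had 0 of 23 pass (5 rose and 2 fell over the list alone), with adjusted p = 8.3e-04, or 0.417 with an estimated correlation. Without a call in neutrophil-like cells were NRF2 targets (0 and 0 of 23, or 1 and 4, adjusted p = 0.401), ATF4 stress genes (0 and 0 of 16, adjusted p = 0.934), inflammasome (0 and 0 of 13, or 1 and 1, adjusted p = 0.349), glycolysis and hypoxia (0 and 0 of 24, adjusted p = 0.647) and disease-associated microglia (0 and 0 of 20, or 2 and 1, adjusted p = 0.867). So were alternative activation (0 and 0 of 15, or 1 and 2, adjusted p = 0.979), antigen presentation (0 and 0 of 15, adjusted p = 0.462), lysosome (0 and 0 of 21, adjusted p = 0.516) and cholesterol efflux (0 and 0 of 10, or 2 and 1, adjusted p = 0.420).

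**Figure D3:**
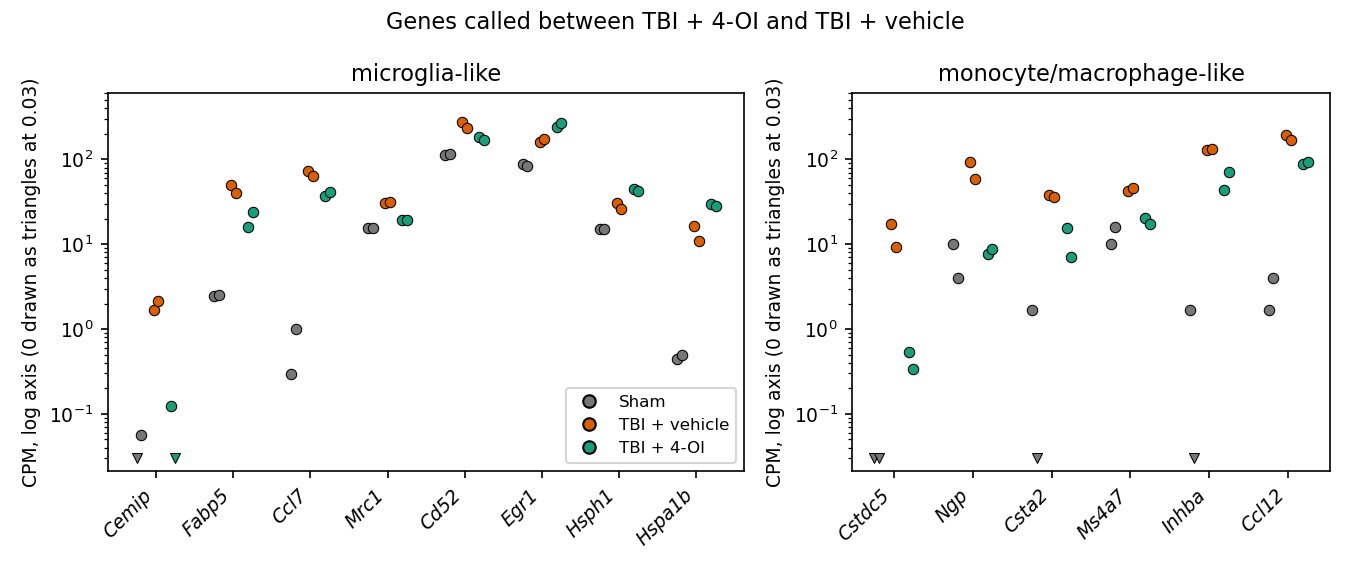
CPM (log axis, 0 drawn as triangles) of the genes called in 4-OI against vehicle in microglia-like and monocyte/macrophage-like cells. Points are single libraries of Sham, vehicle and 4-OI, 2 per group, and Fabp5 in microglia-like cells runs from 2.49 CPM in Sham to 45.3 in vehicle and 20.1 with 4-OI.

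Whether 4-OI moved genes back toward Sham was asked by setting each gene's 4-OI change beside its injury change. Across the 14451 genes of microglia-like cells the correlation was -0.19 (Pearson) and -0.21 (Spearman), and 57.9% of genes had opposite signs. Monocyte/macrophage-like cells gave -0.18 and -0.18 over 10148 genes, with 56.2% of opposite sign, and neutrophil-like cells 0.21 and 0.30 over 10853 genes, with 39.5% of opposite sign. Both changes use the vehicle libraries, which alone makes them correlate negatively. In 20 simulated sets with neither effect and the same sharing, the mean Pearson value was -0.50, -0.28 and -0.34 in the 3 classes. Covariances were -0.0374, -0.0718 and 0.180, against simulated means of -0.0273, -0.0437 and -0.0716. With 1 vehicle library for each change, a test chosen after seeing the data, Pearson values were 0.08 (vehicle library 1 for injury) and -0.10 (library 2) in microglia-like cells. They were -0.09 and 0.01 in monocyte/macrophage-like and 0.27 and 0.30 in neutrophil-like cells, where simulated sets gave -0.05 to 0.04. Genes are not independent replicates, so these values across genes carry no p-value.

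A call in one class and not another does not show that the classes differ, so the 4-OI change in microglia-like cells was tested against that in monocyte/macrophage-like cells of the same 4 libraries. Of 13967 genes 5 passed in edgeR, 3 higher and 2 lower in microglia-like cells, while 690 had an unadjusted p under 0.05 where 698 are due by chance, and DESeq2 called 0 of 23101 genes with 174 such genes where 1155 are due. Csf1, the gene of a growth factor for macrophages, stood at log2 -0.62 in microglia-like and 1.12 in monocyte/macrophage-like cells, a difference of -1.72 ± 0.23 (adjusted p = 0.00407).

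On the mm10 build, with GENCODE vM21 coordinates, Acod1 lies on chromosome 14, 103046977 to 103056573, Hmox1 on chromosome 8, 75093621 to 75100589, Spp1 on chromosome 5, 104435118 to 104441050, Mmp12 on chromosome 9, 7344381 to 7369499 and Fabp5 on chromosome 3, 10012548 to 10016607. Of the genes called with 4-OI, Hspa1b lies on chromosome 17, 34956436 to 34959238 and Egr1 on chromosome 18, 34859823 to 34864984. Ccl7 lies on chromosome 11, 82045712 to 82047525, Mrc1 on chromosome 2, 14229392 to 14332057, Inhba on chromosome 13, 16011851 to 16031621 and Prtn3 on chromosome 10, 79874476 to 79883174. UMIs were counted over whole genes, so no value is tied to an exon.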

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

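Of the tests below, the comparisons at the same mix of microglia or of neutrophil clusters, the fits without vehicle library 1, the fit without the neutrophil clusters marked by granule genes and the comparison with choroid plexus cells were chosen after the result was seen. The biological explanation that the design gives, the treatment of each group, stays open in each pattern.

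Neutrophil marker genes rose in microglia-like cells after injury (11 of 15). The tables argue against droplets that hold a neutrophil and a microglial cell, since microglia-like cells with at least 20 of these UMIs held 2.41% of them (12 of 11457 cells). The risen members stood at a median of 0.0511 times (0.0324 to 0.0880 over members) the UMIs per cell of lymphocyte-like cells in the vehicle libraries, where free RNA would give about equal values. S100a8 had 0.732 UMIs per cell in microglia-like, 11.4 in lymphocyte-like, 3.91 in choroid plexus and 299 in neutrophil-like cells. Lymphocyte-like cells thus held more than free RNA alone gives and are no measure of it. In Sham S100a8 was near equal in microglia-like and choroid plexus cells (0.209 and 0.194), but Hdc was not (0.00133 and 0.0346). In vehicle the risen members stood at 0.206% to 0.658% of the neutrophil-like level, as free RNA could also give. Free neutrophil RNA and expression or uptake by microglia cannot be told apart, and the CD11b sort does not remove neutrophils.

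Immediate early and heat shock genes were placed higher in microglia-like cells with 4-OI. A different mix of microglia clusters is argued against, as the list's median change with the same mix of its 8 clusters in every library of injured mice was 0.26 (quartiles 0.17 to 0.48), against 0.25 with each library's own mix. Handling of the 4-OI libraries that acted on all cells may have raised these genes, as the lists' medians in T, B and NK-like cells, with a median of 0.26 (0.08 to 0.38), were also above 0. T-like cells also carried more neutrophil marker RNA with 4-OI (median 1.85), and a drug that reaches all cells would give the same values, so an effect of 4-OI stays open.

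Granule and cell cycle genes were placed lower in neutrophil-like cells with 4-OI. Without vehicle library 1 or 2 the granule median was -0.66 (-1.21 to -0.40) or -1.03 (-1.24 to -0.83). That of cell cycle genes was -2.29 (-2.78 to -1.64) or -1.06 (-1.34 to -0.47). Each list stayed lower in these fits. Ranges here are quartiles over a list's genes and do not measure spread between libraries. The part of either library in these changes cannot be told apart from an effect of the group. Fewer maturing cells may explain the cell cycle genes, whose median with the same mix of the 5 neutrophil clusters in every library of injured mice was 0.05 (-0.43 to 0.41), against -1.61 with each library's own mix, though these clusters are themselves drawn from such genes and the smallest held 17 cells of a library. For granule genes the same mix gave -0.26 (-0.55 to -0.06) against -0.90, and leaving out clusters 10 and 21 gave -0.95 (-1.36 to -0.48), so fewer maturing cells and lower expression per cell cannot be told apart, and a change of maturation by 4-OI stays open.

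The change with 4-OI differed between microglia-like and monocyte/macrophage-like cells in 5 genes, by edgeR with the library as a block. In simulated data this test recovered 40 of 100 changes of 2-fold and 66 of 100 of 4-fold and called 8 unchanged genes, while here DESeq2 called 0, and 690 genes had an unadjusted p under 0.05 where 698 are due by chance. The differences in log2 change were -1.72 for the growth factor gene Csf1 (adjusted p = 0.00407), 1.41 for Slfn4 (adjusted p = 0.0294), -1.38 for Adgre4 (adjusted p = 0.0294), 1.23 for Lrg1 (adjusted p = 0.0452) and 2.91 for Rbfox1 (adjusted p = 0.0452). Slfn4, Adgre4, Lrg1 and Rbfox1 were chosen after their values were seen, and Adgre4 is a top marker of monocyte/macrophage-like cluster 20, whose part of the class was not held fixed in this test.

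Lymphocyte-like classes, outside the comparisons above, also held changes. After injury edgeR called 57 genes in B-like, 91 in T-like and 6 in NK-like cells. With 4-OI it called 3, 34 and 5. The 3 B-like calls (Ttr, G0s2 and Ccl12) were top markers of choroid-like, neutrophil-like and microglia-like clusters. Ttr and Ccl12 passed there after injury too. RNA of other cells is thus not excluded in B-like or NK-like cells.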

How the results depend on the processing

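The fits without cluster 7, without clusters 10 and 21, with equal cell numbers, with crossed pairing and with split vehicle libraries were chosen after the result was seen. Counts are given as rises and falls, and the cause of a change was not tested except where fewer genes, cells or libraries entered by construction. After injury 113 of 130 counts of calls stayed within 1.5 times, as did 49 of 130 with 4-OI. Shares kept their side of the threshold in 31 of 43 alternatives after injury and 43 of 43 with 4-OI. Camera called 47 of 65 list tests after injury, 10 with an estimated correlation, and fry called 45. List results kept their side in 278 of 325 and 257 of 325, and 5175 of 5436 and 2628 of 2938 values of named genes did.

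With each library left out in turn, injury counts ran from 2156 to 3026 and 1626 to 2632 in microglia-like cells, 829 to 1298 and 351 to 707 in monocyte/macrophage-like cells, and 1243 to 1694 and 708 to 1009 in neutrophil-like cells. With 4-OI they ran from 0 to 11 and 0 to 40, 0 to 11 and 3 to 46, and 0 to 85 and 0 to 151 (edgeR). Log2 share changes after injury ran from -0.40 to -0.18 for microglia-like, 1.43 to 1.92 for monocyte/macrophage-like and 1.61 to 2.65 for neutrophil-like cells. With 4-OI they ran from -0.36 to -0.09, -0.70 to 0.12 and 0.24 to 1.21.

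After injury, a fold threshold of 1.2 gave 1807 and 983 calls in microglia-like cells, and the fit without cluster 7 gave 1626 falls. In monocyte/macrophage-like cells equal cell numbers gave 825 and 445 and DESeq2 441 falls. In neutrophil-like cells equal cell numbers gave 958 and 664, and the fit without clusters 10 and 21 gave 983 and 495. In that last fit 9 of the genes named by the rule changed sign in neutrophil-like cells: Ndufs5 (0.13), Atp5o (0.14), P2ry13 (-0.081), H2-Aa (1.70), Cd74 (2.37), H2-Eb1 (2.45), Hvcn1 (0.0495), Stmn1 (6.62) and Ltf (0.60). The share rise of monocyte/macrophage-like cells stood at 1.65 with the replicate block and 1.80 with TMM over classes, and no longer passed. That of neutrophil-like cells stood at 2.14 with only 2 groups, 2.22 with the replicate block, 2.01 without doublet removal and 2.22 with TMM. Among genes called in either contrast the correlation was -0.24 in microglia-like and -0.37 in monocyte/macrophage-like cells, where sets simulated with neither effect gave -0.50 (-0.55 to -0.45) and -0.30 (-0.38 to -0.19), and 0.22 in neutrophil-like cells, where they gave -0.36 (-0.41 to -0.29). With 1 vehicle library for each contrast it was 0.081 and -0.097 in microglia-like cells, -0.087 and 0.012 in monocyte/macrophage-like cells and 0.27 and 0.30 in neutrophil-like cells (library 1, then 2, for injury), so the negative sign in the first 2 classes depends on which vehicle library enters.

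With 4-OI in microglia-like cells, calls numbered 5 and 49 with DESeq2, 84 and 162 with no low-count filter, 3 and 12 with the replicate block, 0 and 0 with the fold threshold (edgeR) and 1 and 0 without cluster 7. Falls were 2 without doublet removal. In monocyte/macrophage-like cells they were 0 and 3 with DESeq2, 38 and 87 with no filter, 1 and 13 with the replicate block and 5 and 16 with crossed pairing. Rises were 1 without doublet removal and 2 with equal cell numbers. Falls were 2 with only 2 groups, 3 with the fold threshold, 1 each with looser cells, stricter cells and resolution 0.5, and 0 without genes within reach of free RNA (edgeR).

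In neutrophil-like cells calls with 4-OI numbered 0 and 0 (edgeR) with RLE factors, only 2 groups or the fold threshold, and 166 and 171 with DESeq2. They were 290 and 668 with no filter, 55 and 214 with the replicate block, 100 and 304 with crossed pairing, 10 and 43 with looser cells and 34 and 125 with stricter cells. Without doublet removal they were 87 and 226, at resolution 0.5 36 and 126, thinned to equal median depth 48 and 170, without clusters 10 and 21 11 and 45, and with equal cell numbers 1 and 5. Without genes within reach of free RNA 5 rose. The interaction called 0 genes with DESeq2.

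Same-numbered libraries of 4-OI and vehicle did not deviate together (correlations -0.05, -0.19 and -0.28 in the 3 classes). Those of Sham gave 0.12, -0.02 and 0.04 with vehicle and -0.13, 0.08 and 0.23 with 4-OI. The report uses no pairing, as set beforehand, and the replicate block is among the alternatives. Cell number and spread limit the smaller classes: 1.5-fold changes after injury were recovered in 6.15% of simulated genes in monocyte/macrophage-like and 1.49% in neutrophil-like cells, against 65.7% in microglia-like cells.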

Other observations

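The values in this part were chosen after the result was seen. The 2 libraries of each group differ more than a random division of cells gives. Class counts gave a chi-square per degree of freedom of 42.8 (Sham), 53.7 (4-OI) and 38.9 (vehicle), where chance gives 1. Ependymal or choroid-like cells made up 0.598% of 1 Sham library and 3.88% of the other.

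Lymphocyte-like cells made up smaller shares of the CD11b bead-sorted cells after injury. T-like cells fell from 1.76% to 0.813% (log2 -1.11 ± 0.26, adjusted p = 0.0425), B-like cells from 2.16% to 1.03% (log2 -1.06 ± 0.26, adjusted p = 0.0425) and NK-like cells from 0.858% to 0.505% (log2 -0.76 ± 0.22, adjusted p = 0.0486). With 4-OI they stood at 1.28%, 1.55% and 0.792%, and none passed (edgeR adjusted p = 0.290 for each). Most B-like cells of Sham lay in cluster 19 (Vpreb3 and Spib among its top markers) and most of those of vehicle in cluster 16 (Ighd and Fcer2a), so the fall of the class and its gene changes go with different clusters. Share changes of these 3 classes with a library left out are not reported here.

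In T-like cells after injury the chemokine gene Cxcl2 rose by log2 2.83 ± 0.29 (adjusted p = 6.4e-04), the checkpoint receptor gene Ctla4 by 2.18 ± 0.35 and the granzyme gene Gzma by 4.26 ± 0.67 (adjusted p = 0.0123 each). The chemokine receptor gene Cxcr6 fell by 1.82 ± 0.22 (adjusted p = 0.00214). Of glycolysis and hypoxia genes 8 of 23 rose (adjusted p = 5.9e-20, or 0.225 with an estimated correlation). Mitochondrially encoded genes, a sign of RNA quality, were placed higher too (median 0.62, 2 of 11 rose, adjusted p = 4.2e-06, or 0.259 with an estimated correlation). Myeloid genes moved in these cells as well: neutrophil activation genes were placed higher (median 1.81, 3 of 19 rose, adjusted p = 1.9e-14, or 0.177 with an estimated correlation), Il1b, Cd14 and Nos2 rose by log2 3.53, 2.69 and 3.99, and Camp and Ngp fell by 9.26 and 7.32. Free RNA or attached myeloid cells are not excluded as the source of Cxcl2, as lymphocyte-like cells of the vehicle libraries held 11.4 S100a8 UMIs per cell. With 4-OI, 8 of 15 neutrophil markers rose in T-like cells (median 1.85; adjusted p = 3.1e-29, or 0.493 with an estimated correlation).

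The 4-OI libraries against Sham gave 2952 rises and 2523 falls in microglia-like cells, 1231 and 650 in monocyte/macrophage-like cells and 2432 and 2283 in neutrophil-like cells.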
